A study of Caenorhabditis elegans with 6 samples.

How the data were processed

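RNA from whole N2 hermaphrodites aged 5 days was sequenced in 6 libraries, 3 with the perturbation label Y6B3B.9 and 3 with the label L4440. Groups were taken from the perturbation labels, and replicates were numbered within each group in the order of the sample records. Equal numbers were not taken as pairs. Per the labels' protocols, libraries were made with the TruSeq RNA kit v2, which does not record strand. Per the submitters' processing notes, bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and genome build WBcel235 were used. The options, the annotation release and the strand setting are not given in the sources used here.

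The authors deposited raw counts of reads per gene, as whole numbers, for 46748 features, of which 23350 had no read in any library. Total counts per library were 30014150, 29163851 and 23103541 for the label Y6B3B.9 and 27518889, 27813828 and 32012257 for the label L4440. At this depth between 18195 and 20455 genes had a read per library. The reads carry no molecular identifiers, so counting intervals cover counting error only. Of the features, 43693 were matched by ID to a gene name and 46449 to a gene annotation of the same build, from which positions were taken.

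The authors also deposited RPKM values for the same features and libraries. In these values the 6 library totals were recycled along the table instead of being applied library by library: among 4330 genes with at least 1000 reads in all 6 libraries, the gene length implied by count and RPKM was the same over libraries, within 0.1%, for 4330 genes with recycled totals and for 0 genes with each library's own total. As a result 16.7% of the values were divided by their own library's total, and totals differ by up to 1.39-fold. The main tests therefore rest on the counts, and the RPKM values served only for comparison, as deposited and with each library's own total restored. Gene lengths were taken from the ratio of counts to RPKM.

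Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries were scaled by TMM, and groups were compared by the quasi-likelihood test (glmQLFit and glmQLFTest, robust=TRUE) with Benjamini-Hochberg adjustment over the 14265 genes kept and a threshold of 0.05. TMM factors lay between 1.10 and 1.11 for the label Y6B3B.9 and between 0.895 and 0.910 for the label L4440. The common biological coefficient of variation was 5.53%. Standard errors of log2 changes were taken from the F statistic. The level of Y6B3B.9 was also compared by an exact two-sided permutation test. Pairs of libraries of the same group differed by more than sampling noise, with chi-square per degree of freedom between 3.89 and 15.7, so no library was a copy of another. This does not show that they came from separate cultures.

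The design, the alternatives, the 42 gene lists and the rule for named genes were fixed before the data were examined. The text names Y6B3B.9. Among genes past 0.05 with a mean of at least 5 CPM and with no overlap between the groups, it names the 12 largest rises, the 12 largest falls and the 3 smallest p-values in each direction, and for each list up to 4 members with the smallest p, whether or not they passed the test. List members on a side with 5 or fewer were named after their values were seen. Lists with at least 5 tested genes (39 of 42) were tested by camera with a preset correlation of 0.01, adjusted over the lists. A list of mitochondrially encoded genes matched no gene by name, and the 12 genes of that genome were then taken by position. For 36 of the 41 lists with a tested gene, the number of genes past 0.05 adjusted over the list alone equalled that adjusted over all genes, and the largest difference was 2 genes, among neuronal genes.

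Alternatives were DESeq2's size factors, library totals, no filter (at least 1 read), a filter of at least 1 CPM in at least 3 libraries, leaving out each library, robust=FALSE, the Wald test of DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1) on log2(RPKM + 0.1) and log2(RPKM + 1), and for lists camera with an estimated correlation, fry and camera on limma-voom statistics. Added after the data were seen were an alternative that removed a loess trend of log2 change on gene length through offsets, with camera on signed test statistics, and camera on the same statistics with the trend kept. The tests were run on simulated data: counts drawn from the means of the 6 libraries, with 200 genes changed and 14159 genes tested, gave calls for 46 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 10 of 174 calls were of genes not changed. In that simulation few genes changed, with signs drawn at random and without a trend with gene length. In the data 12003 of 14265 genes were called, so the simulation does not show how scaling or false calls behave there. Figures were drawn with matplotlib 3.10.9.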

Results

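Gene expression was measured by RNA sequencing of whole hermaphrodites of *Caenorhabditis elegans* strain N2, the standard laboratory strain, at an age of 5 days. The 6 libraries fell into 2 groups of 3, one whose perturbation label is the gene Y6B3B.9 and one whose perturbation label is L4440, a plasmid known as the empty vector of RNA interference by feeding. The comparison asks which transcripts differ between worms with the 2 labels. The libraries held between 23103541 and 32012257 reads counted in genes. Replicates correlated at Pearson r between 0.994 and 0.996 over log2 CPM of 14084 genes, and libraries of different groups at r between 0.95 and 0.957. Genes are not independent replicates, so these correlations describe agreement across genes.

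Y6B3B.9 itself was higher, not lower, in the libraries labelled with its name. The gene (WBGene00012393) lies on the minus strand of chromosome I at 13734958 to 13751124 in build WBcel235, and its longest annotated transcript has 10 exons and 1722 spliced nucleotides. It took 1057, 1211 and 969 reads in the 3 libraries labelled Y6B3B.9 and 578, 557 and 666 in the 3 labelled L4440. In CPM, counts scaled by library size with TMM factors, its level was 35.8 ± 3.58 (SD, n = 3) against 22.8 ± 0.387 (SD, n = 3), a ratio of 1.57. The fitted log2 change was 0.65 (SE 0.074; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.26e-06), and all 3 libraries labelled Y6B3B.9 lay above all 3 labelled L4440. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Of all tested genes, 63.0% had a lower log2 change than Y6B3B.9. The gene Y6B3B.7 overlaps it on the other strand but took only 41 reads over the 6 libraries. The labels do not say in which direction the gene was perturbed. Every direction below is therefore stated between labels: "higher" and "rose" mean higher in the libraries labelled Y6B3B.9 than in those labelled L4440.

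**Figure D1:**
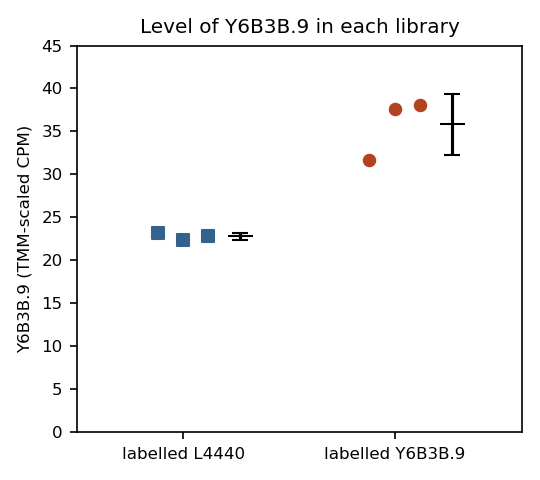
Level of Y6B3B.9 in TMM-scaled CPM (y axis) in each of the 6 libraries by group label (x axis), with points for libraries and, beside them, a bar for the mean ± SD. The 3 libraries labelled Y6B3B.9 average 35.8 CPM and all lie above the 3 labelled L4440, which average 22.8 CPM.

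Most of the measured transcriptome differed between the labels. Of 14265 genes tested, 12003 passed an adjusted p of 0.05 (edgeR), 6623 of them higher and 5380 lower in the libraries labelled Y6B3B.9. A change of at least 2-fold was reached by 3362 of the higher and 1453 of the lower genes, at least 4-fold by 673 and 148, and at least 16-fold by 80 and 1. The split at 2-fold was 2614 higher and 2013 lower with DESeq2's size factors, 4947 and 713 with library totals, and 1988 and 1978 with the trend with gene length described below removed. In 85.4% of the tested genes the 3 libraries of one label did not overlap the 3 of the other, against 10% by chance. The median log2 change of all tested genes was 0.22. Scaling by DESeq2's size factors moved that median by -0.15 and scaling by library totals alone moved it by 0.29. The share of called genes that were higher was 55.2% with TMM scaling, 49.7% with DESeq2's size factors and 67.4% with library totals, so the split between higher and lower rests on the scaling, and changes close to these shifts carry no direction of their own. Genes on a list's side with 5 or fewer members are all named below, those outside the rule for named genes after their values were seen. Of these 69 genes, 10 changed sign with one of these scalings, each of them within 0.29 of 0 with TMM, and 8 changed sign when the trend with gene length described below was removed.

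Among genes with at least 5 CPM, the steepest rises in the libraries labelled Y6B3B.9 were in genes nearly silent in the libraries labelled L4440. ZK354.2 went from 0.441 ± 0.107 CPM (SD, n = 3) under the L4440 label to 98.6 ± 1.49 CPM under the Y6B3B.9 label (log2 change 7.78, SE 0.10, edgeR adjusted p = 8.58e-16). rom-3, of the rhomboid family, had 1435 reads in the libraries labelled Y6B3B.9 and 2 reads in those labelled L4440, both in L4440 replicate 2. Per TMM-scaled library total this was a ratio of 623, with a 95% counting interval of 172 to 5149. The genes dpy-1 and cutl-8, both known for parts in the cuticle, rose by log2 5.40 (SE 0.14) and 5.22 (SE 0.25). ckr-2, a receptor related to those of cholecystokinin, rose by log2 5.18 (SE 0.11), from 1.14 to 41.5 CPM. The others were C17C3.5 (log2 change 8.04), T24A6.7 (6.89), T24F1.4 (6.68), Y43F8A.2 (5.79), R03H10.6 (5.38), ZK177.9 (5.19) and Y53G8AL.1 (4.74). Without L4440 replicate 1 the values were 8.77 for C17C3.5 and 6.68 for Y43F8A.2. T24F1.4, cutl-8 and ZK177.9 each overlap a gene on the other strand, and the library kit does not record strand, so reads of the partner cannot be told from theirs.

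The largest falls included those of pes-10, vet-6, vet-2 and hsp-60. pes-10, a gene transcribed in early embryos, fell from 10.5 ± 1.92 to 0.871 ± 0.448 CPM (SD, n = 3 each; log2 change -3.53, SE 0.25, edgeR adjusted p = 2.87e-08). vet-6 and vet-2, named for very early transcripts of the embryo, fell with log2 changes of -3.04 (SE 0.18) and -2.79 (SE 0.16). hsp-60, the chaperonin of the mitochondrial matrix, fell from 579 ± 17 to 93.6 ± 5.43 CPM (log2 change -2.63, SE 0.056, adjusted p = 2.06e-13 in edgeR), the smallest p of any lower gene. meg-3, a component of germ granules, fell by 2.28 on the log2 scale from 162 CPM, and R09F10.8, which overlaps a gene on the other strand, fell by 2.01 from 163 CPM. The other large falls were T22B2.1 (log2 change -3.35), pap-2 (-2.79), K09E3.7 (-2.64), tag-276 (-2.54), F23D12.2 (-2.49), ccch-5 (-2.48) and the Skp1-related pair skr-10 (-2.57) and skr-9 (-2.56), close copies of each other whose reads could be split between them.

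**Figure D2:**
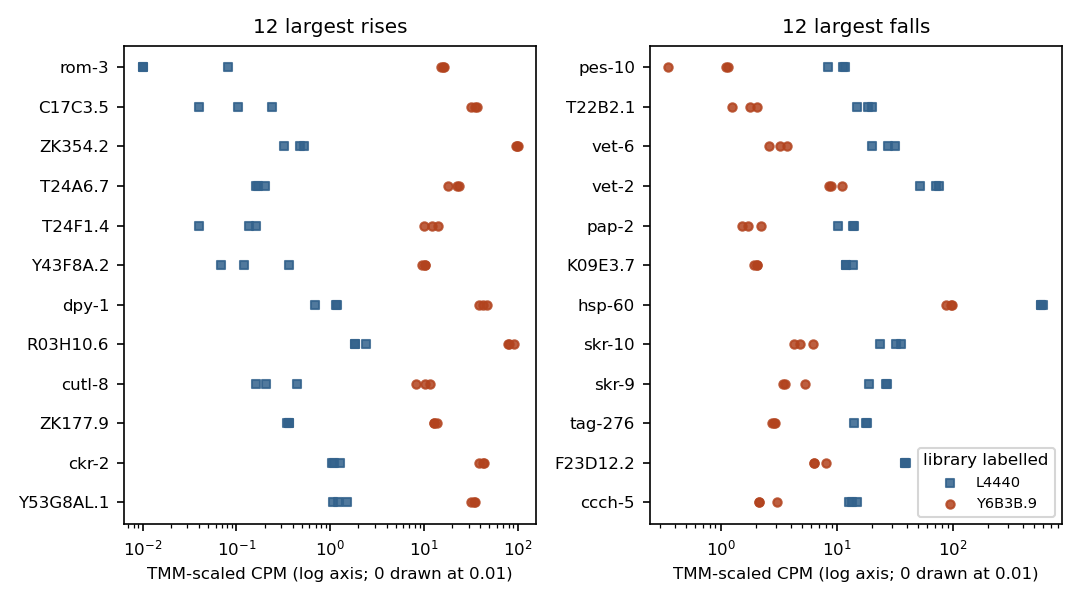
TMM-scaled CPM (x axis, log scale, with a value of 0 drawn at 0.01) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in each of the 6 libraries, squares for the label L4440 and circles for the label Y6B3B.9. These genes were chosen among those whose groups do not overlap, so the gap between labels follows from the choice.

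Genes of oocytes and the germline were lower in the libraries labelled Y6B3B.9. All 32 members of the oocyte and maternal germline list fell, with a median log2 change of -1.07. They included the RNA-binding protein gene car-1 (log2 change -1.79, SE 0.054), the germ granule helicase gene glh-2 (-1.72, SE 0.058), the oocyte yolk receptor gene rme-2 (-1.42, SE 0.052) and the meiotic chromosome gene htp-3 (-1.28, SE 0.048). The list ranked below other genes in camera, a competitive test of a list against all other genes, at an adjusted p of 5.43e-17 with a preset correlation (adjusted p = 0.246 with an estimated correlation). Of 12 eggshell and egg coat genes, 10 fell, among them the chitin synthase gene chs-1 (-1.58), cpg-1 (-1.33), egg-2 (-1.30) and egg-3 (-1.19), while perm-2 (1.06) and perm-4 (1.02) rose (camera adjusted p = 3.73e-06; adjusted p = 0.246 with an estimated correlation). egg-2 has a close copy with which its reads could be shared. Embryonic zygotic genes divided, with 11 of 18 lower, such as sdz-28 (-2.33), tbx-11 (-1.87), die-1 (-1.52) and tbx-9 (-1.33), and 4 higher, namely nhr-25 (1.57), elt-7 (1.22), ceh-51 (1.18, not past the threshold with the length trend removed, at 0.76) and pha-4 (0.94), and the list was not called (camera adjusted p = 0.129).

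Transcripts for small RNA pathways were lower too. Of 42 genes of the small RNA and RNA interference machinery, 39 fell, with a median log2 change of -0.87. Examples were the nuclear Argonaute gene nrde-3 (-1.55, SE 0.051), the mutator genes mut-7 (-1.52) and mut-16 (-1.40) and the polymerase gene ego-1 (-1.36). Only sid-2 (1.38), which acts in uptake of double-stranded RNA from the gut, sid-5 (0.36) and sago-1 (0.16) rose. sid-5 was at -0.32 with the length trend removed and did not pass with DESeq2's size factors (0.21). sago-1 was at 0.0095 with DESeq2's size factors and did not pass without L4440 replicate 1 (0.13) or L4440 replicate 2 (0.12). Camera gave an adjusted p of 5.78e-11 (adjusted p = 0.246 with an estimated correlation).

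Neither the yolk list nor the list of other sperm genes was called as tested. The vitellogenins vit-2, vit-6 and vit-5 rose by log2 0.47, 0.43 and 0.25 and the other 3 of the 6 were not called. Of these, vit-3 had a log2 change of 0.14 (SE 0.065, edgeR adjusted p = 0.0635, with a range from 1.2e-05 to 0.841 over its alternatives). It was at -0.0147 with DESeq2's size factors and passed the threshold without Y6B3B.9 replicate 1 (0.17) or without L4440 replicate 2 (0.18). The list had a camera adjusted p of 0.281. With the length trend removed all 6 were higher, with a median of 0.51, and the list was called (camera adjusted p = 0.00287). vit-5 was no longer past the threshold with DESeq2's size factors (edgeR adjusted p = 0.121, with a range from 2.56e-07 to 0.121 over its alternatives). Vitellogenin reads made up 6.97%, 7.32% and 6.94% of all reads in the libraries labelled Y6B3B.9 and 4.38%, 4.56% and 4.39% in those labelled L4440. Of the major sperm protein genes only 4 passed the filter on low counts, and msp-59 alone was called (log2 change 2.25, at 0.797 against 0.164 CPM). The others, with at most 44 reads per label, had log2 changes of 0.55 (msp-31, SE 0.34), 0.39 (msp-33, SE 0.53) and -0.21 (msp-76, SE 0.47). msp-76 was above 0 with library totals and at 0.41 without L4440 replicate 1, msp-33 was at -0.0773 without Y6B3B.9 replicate 2, and msp-31 passed with library totals (0.84, edgeR adjusted p = 0.0334, with a range from 0.0123 to 0.53 over its alternatives). These genes are near-identical copies, so their counts are uncertain. msp-59 also ends at position 5313111 of chromosome IV, close to ZK354.2, which starts at 5313405 and rose steeply. The kit does not record strand, so reads from beyond the annotated start of ZK354.2 could not be told from those of msp-59. Of 14 other sperm genes, 6 rose (3 higher and 2 lower with the length trend removed), among them spe-41 (2.12), spe-6 (1.05) and spe-15 (0.94), and spe-44 (-0.80) and smz-1 (-0.62) fell (camera adjusted p = 0.325). smz-1 did not pass without Y6B3B.9 replicate 1 (-0.54), Y6B3B.9 replicate 3 (-0.59) or L4440 replicate 2 (-0.39).

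Genes of the cuticle were higher in the libraries labelled Y6B3B.9. Of 129 cuticle collagen genes, 116 rose and 90 of them at least 2-fold, with a median log2 change of 1.81. dpy-14 rose by log2 2.45 (SE 0.10), col-183 by 2.24 (SE 0.12), sqt-3 by 1.97 (SE 0.094) and dpy-17 by 1.81 (SE 0.10), while col-119 (-0.53) fell and so did col-179 (-0.29), the latter above 0 with library totals and not past the threshold without Y6B3B.9 replicate 1 (-0.19), Y6B3B.9 replicate 3 (-0.28) or L4440 replicate 2 (-0.24). Camera gave an adjusted p of 3.70e-09 for the collagens (adjusted p = 0.296 with an estimated correlation). Of 21 molting and larval cuticle genes, 17 rose, such as ptr-4 (2.95, SE 0.16), wrt-10 (2.50, SE 0.11) and mlt-8 (2.34, SE 0.13). The regulators nhr-23 (-1.08) and lin-42 (-1.14), known for timing the molts, fell (camera adjusted p = 0.00275 for the list; adjusted p = 0.395 with an estimated correlation).

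Lists of muscle, neuronal, neuropeptide and intestinal genes ranked above other genes, neuropeptide genes with the highest median. Of 28 muscle genes, 19 rose with a median log2 change of 0.57 over the list, including act-4 (0.96), atn-1 (0.89) and pat-10 (0.85), whereas unc-45 (-1.17), unc-60 (-0.51) and myo-3 (-0.32) fell (camera adjusted p = 0.0138; adjusted p = 0.537 with an estimated correlation). myo-3 did not pass with library totals (-0.0334) or with the length trend removed (-0.003), nor unc-60 on the deposited RPKM with a pseudocount of 0.1 (-0.31). Of 23 neuronal genes, 13 rose, with rimb-1 (2.92), unc-64 (1.21), ida-1 (0.88) and egl-21 (0.84) having the smallest p, and unc-119 (-0.36, at -0.0679 and not past the threshold with library totals) and unc-104 (-0.20) fell. unc-104 was above 0 with library totals and with the length trend removed, and did not pass without Y6B3B.9 replicate 3 (-0.12) or L4440 replicate 3 (-0.18). The neuronal median was 0.51 (camera adjusted p = 0.0334; adjusted p = 0.316 with an estimated correlation). Of 93 neuropeptide genes, 83 rose and 0 fell, the median being 1.07 (52 and 6 with a median of 0.45 when the length trend was removed), with nlp-39 (2.38), flp-15 (2.19), nlp-40 (1.28) and nlp-20 (1.21) as examples (camera adjusted p = 3.73e-06; adjusted p = 0.446 with an estimated correlation). Of 23 intestinal genes, 18 rose, with a median of 0.58, among them the protease gene cpr-3 (1.68), the gut esterase gene ges-1 (1.19), asp-6 (0.94) and act-5 (0.92). cpr-5 (-1.04) and pept-1 (-0.62) fell (camera adjusted p = 0.000138; adjusted p = 0.316 with an estimated correlation). None of these 4 medians changed sign with another scaling.

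Counts of histone genes were also higher. Of 25 tested, 21 rose, with a median log2 change of 1.13, or 16 with a median of 0.42 when the length trend was removed, led by his-62 (2.77), his-67 (2.67), his-60 (1.73) and his-35 (0.95). his-74 (-0.69) fell, as did his-72 (-0.19), above 0 with library totals (camera adjusted p = 0.000104; adjusted p = 0.296 with an estimated correlation). Histone genes are multicopy, so reads may have been divided among copies or left uncounted, and these counts need not follow histone transcript levels.

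All proteasome genes tested and most genes of stress in the endoplasmic reticulum fell. All 33 proteasome subunit genes fell, with a median log2 change of -0.53, among them rpn-1 (-1.15), rpn-9 (-0.96), pas-2 (-0.88) and pbs-5 (-0.82) (camera adjusted p = 3.37e-07; adjusted p = 0.296 with an estimated correlation). Of 29 genes of the unfolded protein response of the endoplasmic reticulum, 18 fell, such as dnj-28 (-1.57), ire-1 (-1.03), hsp-4 (-0.83) and cup-2 (-0.71). The list's median of -0.32 came to -0.0294 with library totals, so that against 0 its direction rests on the scaling. xbp-1 (0.33), dnj-20 (0.26), ckb-4 (0.50), pdi-2 (0.15, below 0 with DESeq2's size factors) and spcs-1 (0.16) rose (camera adjusted p = 0.00813; adjusted p = 0.359 with an estimated correlation). pdi-2 did not pass without Y6B3B.9 replicate 2 (0.13) or L4440 replicate 2 (0.0951), nor spcs-1 without Y6B3B.9 replicate 2 (0.14), L4440 replicate 1 (0.15) or L4440 replicate 3 (0.0907), and spcs-1 was at -0.42 with the length trend removed. That step also ended the calls of xbp-1 (0.0872) and ckb-4 (0.21), and dnj-20 did not pass in the DESeq2 Wald test (0.11). The mitochondrial unfolded protein response list divided evenly, with 9 higher and 9 lower of 19, or 4 and 14 with the length trend removed. Its chaperone and protease genes hsp-60 (-2.63), spg-7 (-1.83) and hsp-6 (-1.71) fell and cdr-2 (1.78) rose (camera adjusted p = 0.0430; adjusted p = 0.349 with an estimated correlation). Cytosolic heat shock genes went both ways, 9 higher and 8 lower of 18, with hsp-17 (1.35) higher and hsp-1 (-1.06), hsf-1 (-1.06) and hsp-110 (-0.95) lower. That list's median was 0.40 while camera placed it below other genes, without a call (adjusted p = 0.797).

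Most genes of central carbon metabolism and oxidative phosphorylation were lower. Of 43 genes of glycolysis and of the tricarboxylic acid and glyoxylate cycles, 35 fell, with a median log2 change of -0.67, among them mdh-2 (-1.52), aco-2 (-1.52), gpd-4 (-1.46) and gpd-1 (-1.43), the last pair close copies. pck-1 (0.98), pyk-2 (0.86), aldo-1 (0.78), gpd-3 (0.74) and gpd-2 (0.36, at 0.0353 and not past the threshold with the length trend removed) rose (camera adjusted p = 3.37e-07; adjusted p = 0.246 with an estimated correlation). Of 52 nuclear-encoded genes of oxidative phosphorylation, 39 fell, with a median log2 change of -0.30 that came to -0.0078 with library totals, so that against 0 its direction rests on the scaling. With the length trend removed 51 were lower and 0 higher. The genes atp-1 (-1.59), atp-2 (-1.35), ucr-2.3 (-1.28) and asb-1 (-1.13) had the smallest p (camera adjusted p = 0.000460 for the list; adjusted p = 0.446 with an estimated correlation). ndub-2 and cox-6C (both 0.19), nduv-2 (0.18) and ucr-2.1 (0.16) rose, but were at 0.0408, 0.0355, 0.0338 and 0.0121 with DESeq2's size factors, not past the threshold, and below 0 with the length trend removed. cox-6C did not pass without Y6B3B.9 replicate 3 (0.0733), L4440 replicate 2 (0.16) or L4440 replicate 3 (0.14), nor ucr-2.1 without Y6B3B.9 replicate 2 (0.13) or L4440 replicate 1 (0.12). Of 12 genes of the mitochondrial genome, found by position after the name search gave none, ND1 (-0.28, above 0 with library totals) and WBGene00010967 (-0.40) fell and 0 rose. ND1 did not pass without Y6B3B.9 replicate 1 (-0.23) or Y6B3B.9 replicate 3 (-0.34), nor WBGene00010967 without any one of Y6B3B.9 replicates 1, 2 and 3 and L4440 replicate 3 (-0.51 to -0.31). With library totals WBGene00010967 was at -0.11.

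Other metabolic lists went both ways. Fatty acid synthesis, desaturation and elongation genes included 19 higher and 7 lower of 29, with dgat-2 (1.69) and fat-6 (1.14) higher and acs-4 (-1.19) and acly-2 (-0.99) lower (camera adjusted p = 0.0843). Beta-oxidation and lipolysis genes divided into 19 higher and 18 lower of 40, with acdh-2 (4.01) and the catalase gene ctl-2 (1.21) higher and kat-1 (-1.29) and acdh-13 (-1.26) lower (camera adjusted p = 0.997). That median, 0.14, turned to -0.0089 with DESeq2's size factors, and with the length trend removed 17 were higher and 20 lower. Of 27 genes of the methionine cycle and one-carbon metabolism, 16 fell, such as tyms-1 (-1.86), sams-3 (-1.33) and pcca-1 (-0.79), and 8 rose, such as cth-1 (0.98) (camera adjusted p = 0.0570). Of 29 sphingolipid genes, 14 rose, including sms-3 (1.34), asah-2 (0.86), gba-1 (0.82) and elo-5 (0.77), and 9 fell (camera adjusted p = 0.249), against 11 higher and 11 lower with the length trend removed. Of 40 autophagy and lysosome genes, 22 fell, such as atg-16.1 (-1.27), vha-12 (-1.09) and epg-3 (-0.96), and sqst-1 (0.99), lgg-1 (0.43), hlh-30 (0.33), vha-3 (0.30) and vha-5 (0.22) rose (camera adjusted p = 0.0568). With the length trend removed lgg-1 was at -0.057 and vha-3 at 0.0318, neither past the threshold, and vha-5 did not pass with DESeq2's size factors (0.0705). The autophagy median of -0.23 turned to 0.058 with library totals. Cytosolic ribosomal protein genes had a median log2 change of 0.24, next to that of all genes, with 52 of 79 higher, such as rpl-25.1 (1.21) and rla-0 (1.12), and 12 lower, such as rps-20 (-1.63) and rpl-12 (-0.91) (camera adjusted p = 0.0138; adjusted p = 0.730 with an estimated correlation). With the length trend removed, 6 ribosomal protein genes were higher and 57 lower, and camera called the list lower than other genes (adjusted p = 0.00287).

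In each of 4 lists of immune genes more genes rose than fell. Of 32 intracellular pathogen response genes, 30 rose, with a median log2 change of 1.35, including rcs-1 (1.51), skr-4 (1.41) and skr-3 (1.35), and drh-1 (-1.08) fell (camera adjusted p = 0.000104; adjusted p = 0.246 with an estimated correlation). Of 67 genes for lysozymes, saposins and antimicrobial peptides, 56 rose, among them spp-2 (1.93), lys-2 (1.14), lys-1 (1.1) and lys-8 (1.00), and spp-17 (-0.56) fell, against 29 higher and 15 lower with the length trend removed (camera adjusted p = 3.73e-06; adjusted p = 0.316 with an estimated correlation). Of 105 C-type lectin genes, 81 rose and 8 fell (61 and 13 with the length trend removed), with clec-62 (1.17), clec-84 (1.16) and clec-41 (1.15) higher and clec-88 (-1.11) lower (camera adjusted p = 3.18e-05; adjusted p = 0.246 with an estimated correlation). Of 24 PMK-1 and intestinal innate immune genes, 16 rose, such as tir-1 (2.22), zip-2 (1.73), C17H12.8 (1.32) and lys-2, and 6 fell (camera adjusted p = 0.00151; adjusted p = 0.246 with an estimated correlation).

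In the lists of cytochrome P450, glucuronosyltransferase, glutathione S-transferase and metal response genes more members rose than fell. Of 63 cytochrome P450 genes, 42 rose and 11 fell, with cyp-35B1 (2.14), cyp-36A1 (1.53), cyp-33C8 (1.48) and cyp-34A9 (1.32) having the smallest p (camera adjusted p = 0.00881; adjusted p = 0.246 with an estimated correlation). Of 59 UDP-glucuronosyltransferase genes, 40 rose and 6 fell, led by ugt-39 (2.46), ugt-50 (1.28), ugt-25 (1.1) and ugt-62 (0.77) (camera adjusted p = 0.00188; adjusted p = 0.258 with an estimated correlation). Of 39 glutathione S-transferase genes, 33 rose (18 higher and 4 lower with the length trend removed), among them gst-24 (3.38, SE 0.071), gst-29 (1.83) and gst-39 (1.2), and gst-7 (-0.95) and gst-1 (-0.29, at -0.0025 and not past the threshold with library totals) fell (camera adjusted p = 0.00133; adjusted p = 0.296 with an estimated correlation). Of 16 metal response genes, 13 rose and 0 fell (9 higher and 3 lower with the length trend removed), with cdr-2 (1.78), the metallothionein gene mtl-1 (1.1), cdr-4 (1.04) and the ferritin gene ftn-2 (0.92) as examples (camera adjusted p = 0.00181; adjusted p = 0.316 with an estimated correlation). Of 23 SKN-1 and oxidative stress genes, 16 rose, such as mxl-3 (1.33) and gst-6 (1.11), or 11 with the length trend removed, and 5 fell, namely gsr-1 (-1.01), gst-7, skn-1 (-0.50), wdr-23 (-0.20) and gcs-1 (-0.17), the last pair above 0 with library totals and gcs-1 not past the threshold with the length trend removed (camera adjusted p = 0.214). Antioxidant enzyme genes included 16 higher and 6 lower of 28, with gpx-5 (1.4), ctl-2 (1.21) and sod-4 (0.91) higher and sod-2 (-0.67) lower (camera adjusted p = 0.208). With the length trend removed, 6 were higher and 14 lower.

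Genes induced and genes repressed by DAF-16, a transcription factor of insulin signalling, both rose for the most part. Of 24 genes induced by DAF-16, 18 rose, such as cpi-1 (1.35), ctl-2 (1.21) and stdh-1 (1.16), the list's median being 1.16 as tested and 0.56 with the length trend removed, and lea-1 (-1.94), aqp-1 (-0.78), sip-1 (-0.67) and daf-16 itself (-0.49) fell (camera adjusted p = 0.00282; adjusted p = 0.296 with an estimated correlation). Of 18 genes repressed by DAF-16, 15 rose, such as thn-2 (1.99), dod-19 (1.43), ges-1 (1.19) and clec-41 (1.15), and acdh-1 (-1.43), dod-24 (-0.22) and asp-13 (-0.16) fell, the last pair above 0 with library totals (camera adjusted p = 0.00174; adjusted p = 0.246 with an estimated correlation). asp-13 did not pass without L4440 replicate 2 (-0.12). Of 31 ageing and longevity regulators, 18 fell, such as daf-18 (-1.53), tcer-1 (-1.28), age-1 (-1.2) and hsf-1 (-1.06), and 12 rose (camera adjusted p = 0.0456; adjusted p = 0.316 with an estimated correlation). Of 14 hypoxia response genes, 8 rose, among them nhr-57 (1.04), cysl-1 (1.02) and phy-2 (0.90), and egl-9 (-0.59), vhl-1 (-0.30) and rhy-1 (-0.29, above 0 with library totals) fell (camera adjusted p = 0.208). vhl-1 was at -0.0083 with library totals and did not pass there, nor without Y6B3B.9 replicate 2 (-0.30), Y6B3B.9 replicate 3 (-0.27) or L4440 replicate 3 (-0.26), nor rhy-1 without Y6B3B.9 replicate 1 (-0.17) or L4440 replicate 3 (-0.27). egl-9 did not pass on the deposited RPKM (limma adjusted p = 0.124 with a pseudocount of 0.1, with a range from 7.78e-22 to 0.133 over its alternatives). The only other tested gene of the target's clone, Y6B3B.1, rose from 0.493 to 1.59 CPM (log2 change 1.66, SE 0.26).

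**Figure D3:**
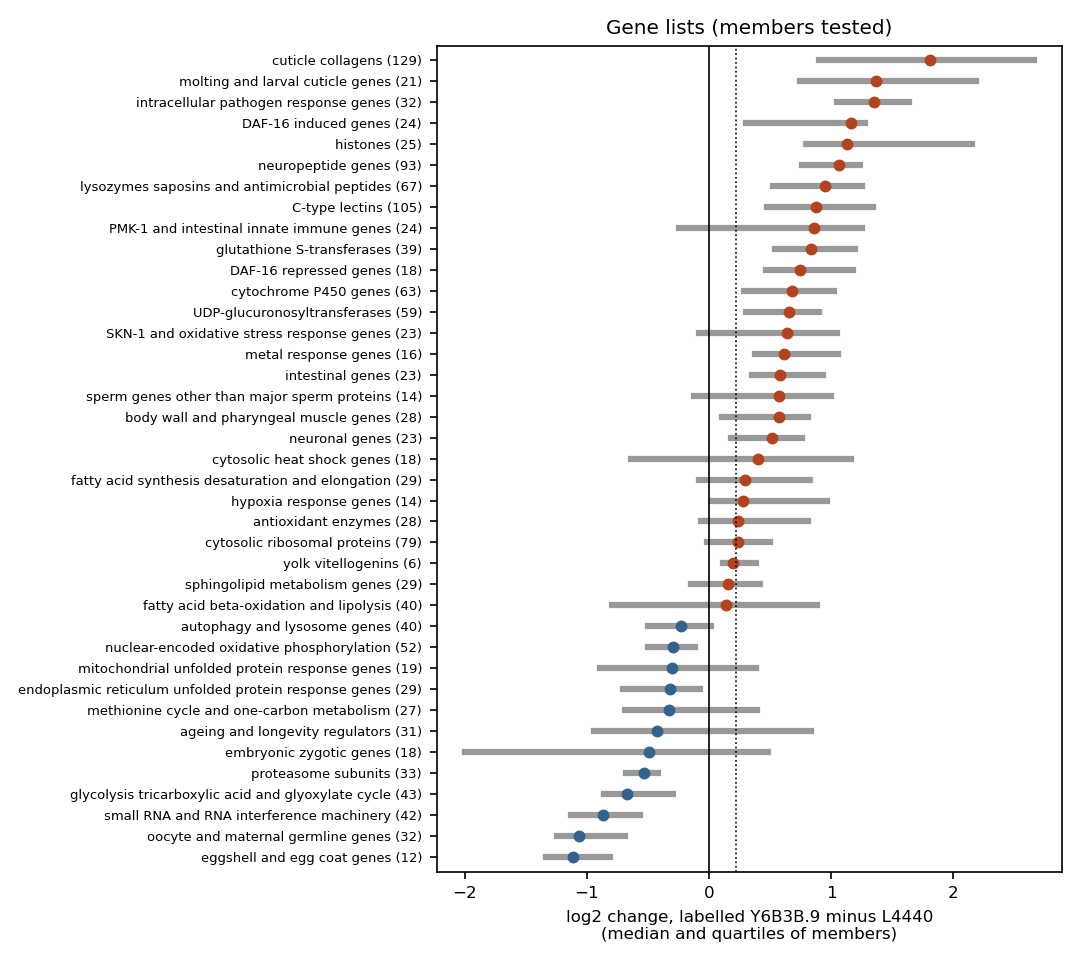
Median log2 change (points) and quartiles (bars) of the tested members of the 39 gene lists with at least 5 tested genes, libraries labelled Y6B3B.9 minus L4440 on the x axis, with the number of members in brackets. The solid line marks 0 and the dotted line the median of all tested genes, 0.22. Collagens lie highest at 1.81 and the eggshell and oocyte lists lowest at -1.12 and -1.07. The medians of beta-oxidation genes and of autophagy genes change sign with another scaling.

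The changes also moved with gene length. The counts do not show whether this trend is technical, from RNA quality or library preparation, or a change in the worms' transcripts, and the values of lists of short or long genes depend on it. The median log2 change was 0.81 among the shortest eighth of genes and -0.53 among the longest, and Spearman's rho between log2 change and length was -0.30 across 14265 genes. Within lists, rho was -0.63 among 28 muscle genes, -0.45 among 32 oocyte and germline genes and -0.30 among 79 ribosomal protein genes. A change of tissue shares that moved the members of a list alike would not give a trend within that list. Other changes in the worms' transcripts could. Each library labelled Y6B3B.9 had relatively more reads on short genes (rho between -0.22 and -0.33 across genes) and each library labelled L4440 relatively fewer (rho between 0.25 and 0.31). Levels were taken relative to each gene's mean over all libraries, so the opposite signs of the groups are not separate observations. Neuropeptide, histone and antimicrobial genes, with median lengths of 542, 470 and 429 nucleotides, stood on the short side, and small RNA machinery genes, with a median of 2979 nucleotides, on the long side. With the trend removed, a step chosen after the data were seen, the medians were 0.45 for neuropeptides, 0.42 for histones, 0.29 for antimicrobial genes, 1.43 for collagens, -0.79 for small RNA machinery and -1.1 for oocyte genes. The medians of ribosomal protein genes (-0.35), antioxidant enzymes (-0.21), beta-oxidation genes (-0.15) and the 4 major sperm protein genes (-0.28) turned negative. The same step left 43.9% of called genes higher and moved the median of all genes by -0.29, to -0.0759. Camera, run for this on signed test statistics, kept the call and direction of 24 lists. The call of ribosomal proteins reversed. Ageing regulators (adjusted p = 0.491) and the mitochondrial unfolded protein response (adjusted p = 0.0741) were no longer called. Yolk genes were called higher and autophagy genes lower (adjusted p = 0.00287 for each). On the same statistics with the trend kept, adjusted p was already 0.0991 for ageing regulators, 0.318 for the mitochondrial unfolded protein response and 0.0112 for autophagy genes, and 0.184 for yolk genes.

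**Figure D4:**
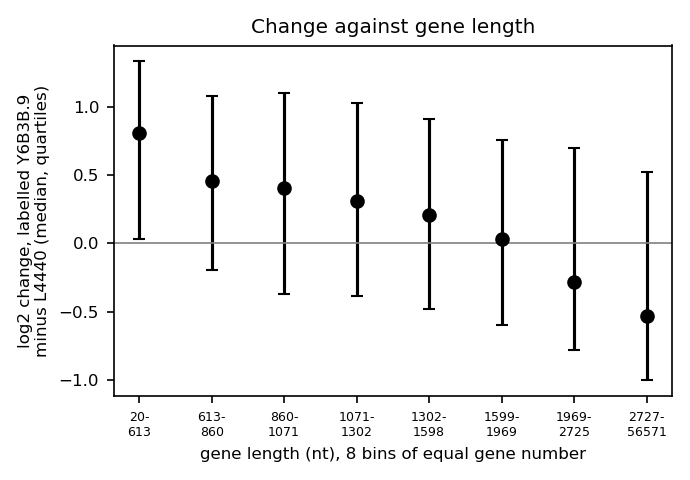
Log2 change between libraries labelled Y6B3B.9 and L4440 (y axis, median and quartiles) in 8 bins of nearly equal gene number by gene length in nucleotides (x axis). The median falls from 0.81 in the shortest bin to -0.53 in the longest.

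In splits of the libraries that mix the labels, which still hold part of the label difference, camera called up to 27 lists at the preset correlation. With the libraries grouped by label it called 27 of 39. It called 0 with the correlation estimated from the 6 libraries, where 6 lists had an unadjusted p under 0.05, while fry, which asks whether a list's genes move on balance one way without reference to other genes, called 39. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.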

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

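The length correction, camera on signed statistics and the RPKM with each library's own total were chosen after seeing the data; the other alternatives were planned. No paired analysis was run, because the labels carry no replicate numbers. The sample records alternate between the labels, but this order was not taken as a pairing. Y6B3B.9 stayed higher in the libraries labelled Y6B3B.9 and past the threshold in all 17 alternatives, with log2 changes from 0.50 to 0.94 and adjusted p up to 0.0023. Leaving out 1 library at a time gave log2 changes of 0.60 to 0.73 for this gene, 11560 to 12050 called genes, 4823 to 5145 called genes with at least a 2-fold change, and 27 to 30 gene lists. The count with at least a 2-fold change was 2711 with limma-trend on log2(RPKM + 1), where the larger pseudocount shrinks the change of low genes, against 4815. The count of gene lists was 0 with camera's estimated correlation, against 27; its lowest adjusted p was 0.246, 6 lists had an unadjusted p under 0.05, and fry gave 39, camera on limma-voom statistics 27 and on signed edgeR statistics 26. Of 4024 values for the 237 other named genes, 178 by rule and 59 after their values were seen, 3816 kept direction and call, 154 lost the call (in 38 genes; of these egl-9, unc-60, col-119, daf-16, pept-1, spp-17, skn-1 and wdr-23 on the deposited RPKM), 11 gained it (vit-3 and msp-31) and 43 reversed. The reversals were in 21 genes, 17 of them past the threshold as reported. With library totals col-179 turned to 0.0017, rhy-1 to 0.00041, ND1 to 0.0072, dod-24 to 0.0759, msp-76 to 0.0808, wdr-23 to 0.0921, unc-104 to 0.0929, his-72 to 0.10, gcs-1 to 0.12 and asp-13 to 0.13. With each library's own total in RPKM, ND1 was at 0.0129, dod-24 0.0762, unc-104 0.0805, wdr-23 0.0916, his-72 0.10, gcs-1 0.12, asp-13 0.13 and msp-76 0.26. On log2(RPKM + 0.1) and log2(RPKM + 1), his-72 was at 0.0086 on both, gcs-1 at 0.0275 and 0.0272, asp-13 at 0.0366 and 0.0364, and msp-76 at 0.19 and 0.0574. With DESeq2's size factors and its Wald test, vit-3 was at -0.0147 and pdi-2 at -0.0016 in both, and with limma-voom msp-76 at 0.0472. With the length trend removed, 5 genes were past the threshold in the other direction, spcs-1 (-0.42), ndub-2 (-0.34), sid-5 (-0.32), nduv-2 (-0.25) and cox-6C (-0.61), and ucr-2.1 (-0.0759), lgg-1 (-0.057), msp-31 (-0.25), msp-33 (-0.32) and unc-104 (0.13) changed sign without passing it. When 1 library was left out, msp-33 lay between -0.0773 and 0.88 and msp-76 between -0.65 and 0.41. The cause was not tested. Scaling moved the share of higher genes more than the number of calls, from 49.7% with DESeq2's size factors to 67.4% with library totals. Depth limits the genes with few reads in the libraries labelled L4440, such as rom-3, whose ratio is known only between 172 and 5149.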

Other observations

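The tests of gene length, of germline share, of exchanged labels and of reads from bacteria were chosen only after the result was seen, and the tests of genes upstream and of other splits before. Genes at least 16-fold higher in the libraries labelled Y6B3B.9 numbered 80. Examples were the chemoreceptor gene srx-13 (log2 change 5.77), the receptor gene ntr-1 (4.03), the linker histone gene hil-7 (4.37), the lipocalin-related gene lpr-6 (4.33) and the molting gene mlt-4 (4.25), all chosen after their values were seen, and no class of genes was tested for enrichment among the 80. By annotation 68 were protein-coding, 8 pseudogenes and 4 noncoding RNA genes, and 5 of the 80 had no read in any library labelled L4440. Of the 80, 7 belonged to a gene list fixed in advance, a share that was not compared with that of all tested genes. Genes of this set were noticed next to each other before they were counted, and formed 8 neighbouring pairs of tested genes, against at most 4 in 10000 random draws of 80 genes. The draws came from all located tested genes and were not matched for the low level of the 80 under the L4440 label. They therefore do not show whether other genes as low lie together as often. Among all tested genes, 31 of 39 long intergenic noncoding RNA genes were higher and 3 lower, or 79.5% higher, against 46.4% higher and 38.3% lower among protein-coding genes. Of 436 pseudogenes, 45.2% were higher and 26.1% lower. These shares were not tested against each other or matched for gene length. Of the 1784 genes in the shortest eighth, 1154 were higher and 288 lower.

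Y6B3B.9 was higher in the libraries labelled with its name, by 8.75 times the standard error of its log2 change. An exchange of the labels of both groups as a whole would need such a difference, and so would a true rise, so the 2 cannot be told apart from counts alone. A lower share of germline tissue cannot be told apart either, since the gene's log2 change of 0.65 lay within the interquartile range of 74 muscle, neuronal and intestinal genes (0.14 to 0.85), but so did 22.7% of all tested genes. Reads from a copy of the gene carried by the worms' food bacteria stay open too, since the gene stood at percentile 64.9 of those 74 genes and counts per gene do not show where in the gene the reads lie. The biological difference named by the labels is untested among these.

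Germline lists were lower and somatic lists higher in the libraries labelled Y6B3B.9. The median of the cuticle collagens exceeded that of the 74 muscle, neuronal and intestinal genes by 1.28 on the log2 scale. The permutation p was 1e-05, the smallest 100000 resamples can give, but genes are not independent replicates. With the length trend removed the excess was 1.05. A lower share of germline tissue that raised all somatic genes alike would not give such an excess. Some of the 74 genes fell, such as unc-45 and cpr-5, so their median need not equal the rise of a purely somatic transcript. The test shows that collagens rose more than these genes, but does not exclude a lower share of germline tissue for the collagens. The trend with gene length does not account for the difference between these lists, since the median of the 74 genes exceeded that of 44 oocyte and eggshell genes by 1.6 before and by 1.49 after the trend was removed (permutation p = 1e-05 for each). For the muscle, neuronal and intestinal lists a lower share of germline tissue stays open: their medians differed by at most 0.068 (permutation p = 0.912 with members exchanged between lists), which does not show that they moved alike, as the upper end of a 95% bootstrap interval of that difference was 0.48. The neuropeptide median exceeded that of the 74 genes by 0.53 (permutation p = 1e-05), but by 0.0665 with the length trend removed (permutation p = 0.213), so for these genes it stays open too, as does the biological difference named by the labels, which is untested.

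The genes at least 16-fold higher were examined for transcription running on from a gene upstream and for the trend with gene length. That trend alone is too small to give them, since the median log2 change ran only from 0.81 in the shortest to -0.53 in the longest eighth of genes. With the trend removed the median log2 change of the 80 was 4.51, and 61 were still at least 16-fold higher. As they were chosen for changes at least that large, this outcome was nearly fixed by the choice. An snRNA gene ended within 5 kb upstream on the same strand for 0 of the 80 (exact Clopper-Pearson 95% bound 4.51%), against 33 of 14086 other genes (Fisher's exact test, p = 1). A same-strand gene of at least 10 CPM ended within 2 kb upstream for 11.2% of them (95% bounds 5.28% to 20.3%), against 13.1% of 4164 genes as low in the libraries labelled L4440 (Fisher's exact test, p = 0.739). Both shares are too uncertain to exclude run-on and other windows were not tested, so run-on stays open. The 8 neighbouring pairs do not bear on it as a set, since they were counted without regard to strand or distance. Among the 80, sri-43 and T10D4.15 lie close together on opposite strands and point away from each other. Others lie close together on the same strand, such as srx-13 and srx-14, T07D10.1 and WBGene00194657, and ZK262.8 and ZK262.9. No gene of these same-strand pairs reached 10 CPM under either label, so the upstream test could not count it as a source. The biological difference named by the labels stays open too and is untested.

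With 3 against 3 libraries there are 10 ways to split the 6, too few for a share under 0.05. The real split gave 12003 genes, 4815 of them with at least a 2-fold change, and the highest of the other 9 splits gave 0 of either, so 1 split of 10 gave as many genes. In those 9 splits each side holds libraries of both labels. The label difference then enters the spread within sides, so few calls could follow and the 0 carries little information. For gene lists the real split gave 27 and the highest other split also 27, so 2 of the 10 splits gave as many lists. Camera at a preset correlation calls between 18 and 27 lists in splits that mix the labels, where edgeR calls 0 genes and between 3 and 38 genes have an unadjusted p under 0.05. Such splits still set 2 libraries of a label against 1. Their list counts therefore hold part of the label difference and do not measure calls without it.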
